A study of Mus musculus with 24 samples.

How the data were processed

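The series compared astrocytes sorted by fluorescence from the olfactory bulb, hippocampus, cortex and thalamus of control mice and of mice with a conditional knockout of Nfix. There were 3 libraries for each of 4 regions and 2 genotypes, 24 in 8 groups, and no column of any other sample was used. Region and genotype came from the tissue and genotype labels, and replicate numbers from the sample titles. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The Cre driver, the exons deleted, age, sex and batches were not given in the sources used here.

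Per the labels' protocols, RNA of the sorted cells was purified with a micro column kit and checked on a capillary fragment analyser, and libraries with single 8-bp indices were made from 10 ng of RNA with the Revelo RNA-seq High Sensitivity kit. No molecular identifiers are described. The submitters' processing notes name FastQC 0.10.1, MultiQC 0.9, STAR 2.5.0a, R 3.5.2, DESeq2 1.20.0 and the mouse build mm10. The counting tool, the annotation and the use of strand were not given in the sources used here, so reads of a gene and of an antisense or overlapping gene cannot be told apart.

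The deposited table holds one signal value per gene and library, which the authors had made by dividing read counts by one size factor per library, as the values themselves show. In every library 100% of values were whole multiples of the smallest value above 0 within 0.001. The factors read from these steps equalled median-of-ratios factors computed again over the 957 genes above 0 in all 24 libraries, with a difference of 0%. For the count tests whole reads were recovered in 22 columns. Thalamus WT replicate 1 and thalamus KO replicate 3 also had whole multiples throughout, but 1 read was worth 0.993 and 9.90 there, and a separate check of the columns does not cover steps close to 1 or 10. These libraries were therefore kept out of the count tests, and their reads are given as the values divided by that step. Of 24421 entries, 27 were named as calendar dates, held at most 0.255% of a library's reads and were left out, leaving 24394 genes. No mitochondrially encoded gene was in the table. The ribosomal RNA gene Rn45s took 6.54 to 12.7% of the reads. Libraries held 2522171 to 25667980 reads, and a floor of 3 reads per gene is given in CPM.

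The test fixed beforehand was edgeR's quasi-likelihood test on raw counts. Because the values were already normalized, limma-trend was used in its place, with lmFit and eBayes (trend and robust) on log2(value + 10), for genes with a value of at least 10 in at least 3 libraries. Fold changes are on the log2(value + pseudocount) scale, which understates the change of low genes. Calls had a Benjamini-Hochberg adjusted p under 0.05. KO was compared with WT within each region on its 6 libraries, the KO against WT difference was compared between regions by an F test of the interaction, and regions were compared within the 12 WT libraries. These comparisons, the rule for named genes, the gene lists and most alternatives were fixed before the data were examined. The average over regions, the repeats without the libraries with few detected genes and with the hippocampus pair averaged, the pseudocounts of 1 and 100, the TMM factors and the array weights were chosen after seeing the data. For single genes and few libraries exact permutation tests enumerated the assignments of libraries within regions.

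Before use, the tests were run on simulated counts with 200 genes changed 2-, 4- or 8-fold. At a low dispersion of 0.05, limma called 100% of 8-fold genes in every comparison and, in the olfactory bulb comparison (11603 genes), 67.2% of 2-fold genes. At the spread of the data it called 15.2% of 8-fold genes in the olfactory bulb (9738 genes), 25.8% in the hippocampus (9696 genes), 0% in the cortex (8633 genes), 7.58% in the thalamus (8690 genes) and 62.1% in the average over regions (13356 genes). It called 0% in the interaction (13379 genes) and 0% between the WT regions (11952 genes). The simulated spread followed the trend over abundance and not each gene's own spread. Genes with a smaller spread can therefore pass at smaller differences. In the data, Clu passed between the WT regions at 1.77 and Slc6a11 at 2.86 (log2 difference of the highest and lowest regions). The median standard error of a log2 difference was 1.49 in the olfactory bulb, 1.41 in the hippocampus, 2.12 in the cortex, 2.31 in the thalamus and 0.81 in the average.

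There were 32 gene lists, 18 of pathways and 14 of cell type markers, tested with camera in limma at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjusted p-values of camera are over the lists of one comparison. The report prints members for the NFI, GABA, purinergic and astrocyte identity lists and for lists with a call, and counts for the others. Named genes were Nfix, then genes with an adjusted p under 0.05, a mean of at least 5 CPM and groups that did not overlap (the 10 largest rises, the 10 largest falls and the 5 most abundant), up to 4 members of each list with the smallest p, and up to 10 genes of the interaction. Where no gene but Nfix passed, the 10 genes with the smallest p were named as not passing. Symbols of predicted genes were not named, and some genes that the rule names are not reported here. For the WT regions the rule was extended to the 10 smallest adjusted p, with the other called genes given by name. Coordinates are from GENCODE vM21 on GRCm38. Of 75 annotated genes named or plotted, 35 had an exon overlapped by another annotated gene, whose whole span was used, introns included.

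Alternatives were RLE, upper-quartile and TMM factors, DESeq2, limma-voom and edgeR on the recovered reads, no filter and a filter at 5 CPM, no robust estimation, the replicate number as a block, all libraries in one model, haemoglobin (10) and ribosomal protein (84) genes left out, pseudocounts of 1 and 100, array weights, and each library left out in turn. Other splits of the libraries were counted over all 10 splits of 3 against 3 and over 100 drawn splits elsewhere. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.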

Results

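Gene expression was measured by bulk RNA-seq in astrocytes sorted from 4 regions of the mouse brain, the olfactory bulb, hippocampus, cortex and thalamus. Each region contributed 3 libraries from control mice (labelled WT) and 3 from mice with a conditional knockout of Nfix (labelled KO), 24 libraries in all. Nfix encodes nuclear factor I X, a transcription factor of the NFI family that acts in glial development. The series title places the work in thalamocortical circuits and names GABA and purinergic signalling, and the design asks which genes differ between knockout and control astrocytes in each region. Levels are given as normalized read counts, the reads of a gene divided by the size factor of its library. Libraries held 2522171 to 25667980 reads assigned to genes. A gene had to hold 3 reads to lie above the counting floor, which was 0.117 reads scaled to a common library total (CPM) in the deepest library (hippocampus WT replicate 2) and 1.19 CPM in the shallowest (thalamus KO replicate 3). These floors cover counting error only, because reads without molecular identifiers are not independent molecules.

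Nfix was the targeted gene, and its level was higher in the libraries labelled KO than in those labelled WT in each of the 4 regions as deposited, a direction that turned in the cortex under upper-quartile scaling (log2 difference -1.53). In the olfactory bulb it stood at 2448 ± 96.8 normalized reads in WT and 4693 ± 1347 in KO (SD, n = 3 each). The hippocampus gave 4512 ± 608 and 6730 ± 1253, the cortex 3786 ± 557 and 5026 ± 748, and the thalamus 3137 ± 440 and 6947 ± 4403. Of the 12 libraries labelled KO, 10 lay above every WT library of their region. The exceptions were cortex KO replicate 2 (4230, with WT replicate 3 at 4402) and thalamus KO replicate 3 (3009, from 304 reads). The log2 differences were 0.90 (SE 0.50), 0.57 (SE 0.41), 0.41 (SE 0.87) and 0.94 (SE 1.27) in the order above, and none passed in limma (adjusted p from 0.854 to 1.00). With hippocampus WT replicates 2 and 3 averaged, the hippocampus gave 0.52 (SE 0.49, limma, adjusted p = 0.998). The thalamus difference was 1.44 without KO replicate 3, and the cortex difference was 0.52 without WT replicate 3. An exact two-sided permutation test within a region gave p = 0.1 in the olfactory bulb and hippocampus and p = 0.2 in the cortex and thalamus, where 3 libraries against 3 cannot go below 0.1. Averaged over the regions with genotype permuted within each, the difference was 0.70 and the exact two-sided p was 0.0001375 over 160000 assignments. This permutation takes all libraries as independent, which the labels do not show, and counts hippocampus WT replicates 2 and 3 as separate. Nfix lies on chromosome 8 at 84699876 to 84800344 on the minus strand (GRCm38) with 13 merged exons. A value per gene cannot tell reads of deleted exons from reads of the remaining ones, so these values check the labels only in part. Its exons overlap the spans of the antisense genes Lyl1 and G430095P16Rik. Lyl1 was at 0 in 21 of 24 libraries, with a maximum of 396.5 normalized reads.

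**Figure D1:**
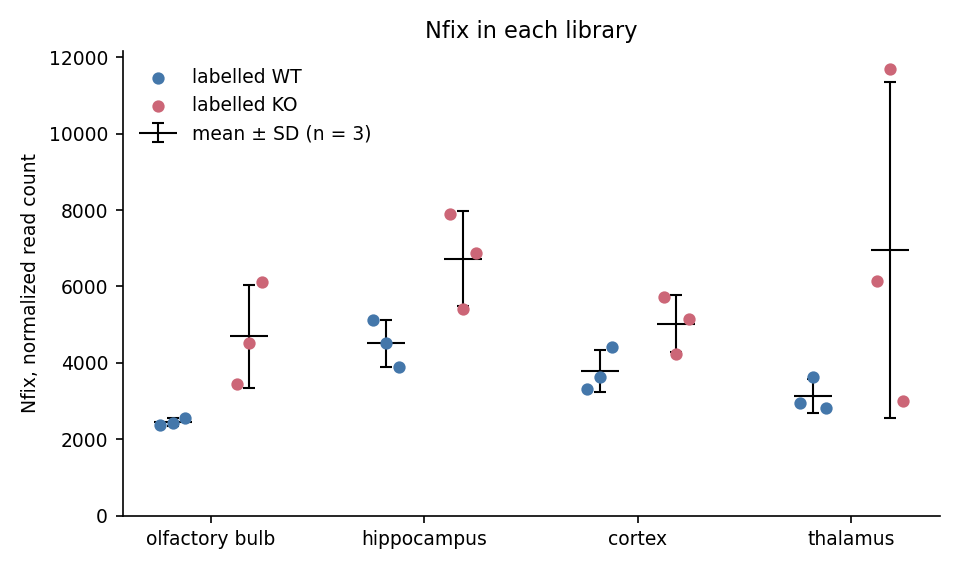
Nfix in normalized read counts (vertical axis) for each library, by region and genotype label (horizontal axis), with the group mean as a line and the SD as whiskers (n = 3). Group means as deposited were higher for KO than WT in all 4 regions, turning in the cortex under upper-quartile scaling (-1.53), and 10 of 12 KO libraries lay above every WT library of their region.

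The other NFI genes, Nfia, Nfib and Nfic, showed no difference that passed. In the olfactory bulb 4 of 4 family members lay above 0, with log2 differences of 0.98 (SE 0.72) for Nfic, 0.20 (SE 0.38) for Nfia and 0.14 (SE 0.43) for Nfib. The hippocampus had 2 above and 2 below, the cortex 1 above and 3 below, and the thalamus 2 above and 2 below. Nfia stood at 7230 ± 2450 in WT and 7994 ± 1118 in KO olfactory bulb, and at 6935 ± 1892 and 19080 ± 15033 in the thalamus, where the KO mean rested on KO replicate 3 and the other KO libraries held 11388 and 9449. No member passed adjusted over the list alone in any region (0 of 4 in each by limma), and Nfix itself reached an unadjusted p of 0.0745 in the olfactory bulb.

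Astrocyte transcripts were lower in cortex WT replicate 3 and thalamus KO replicate 3, where the summed astrocyte markers took 17785 and 10759 CPM, than in the other 22 libraries (31348 to 93573 CPM). These libraries held reads for 3871 and 2220 genes, against 7509 to 11984 in the others. Mbp, which encodes myelin basic protein, took 48468 CPM in cortex WT replicate 3 and 66346 CPM in thalamus KO replicate 3. Aqp4, the water channel of astrocyte endfeet, stood at 31.6 CPM in the former and at 0 in the latter. The summed oligodendrocyte markers averaged 20223 ± 27917 CPM in cortex WT and 9123 ± 8384 in cortex KO, and 9695 ± 3066 in thalamus WT and 36537 ± 37036 in thalamus KO. In the hippocampus they averaged 4151 ± 1368 CPM in WT and 3711 ± 3625 in KO, and in the olfactory bulb 4178 ± 506 and 3841 ± 1771. Summed astrocyte markers ran from 31687 ± 18188 CPM in thalamus KO to 82786 ± 4087 in hippocampus WT. The 100 most abundant genes took 57.6% of the reads of thalamus KO replicate 3 and 35.3 to 43.1% of those of the other 23 libraries.

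**Figure D2:**
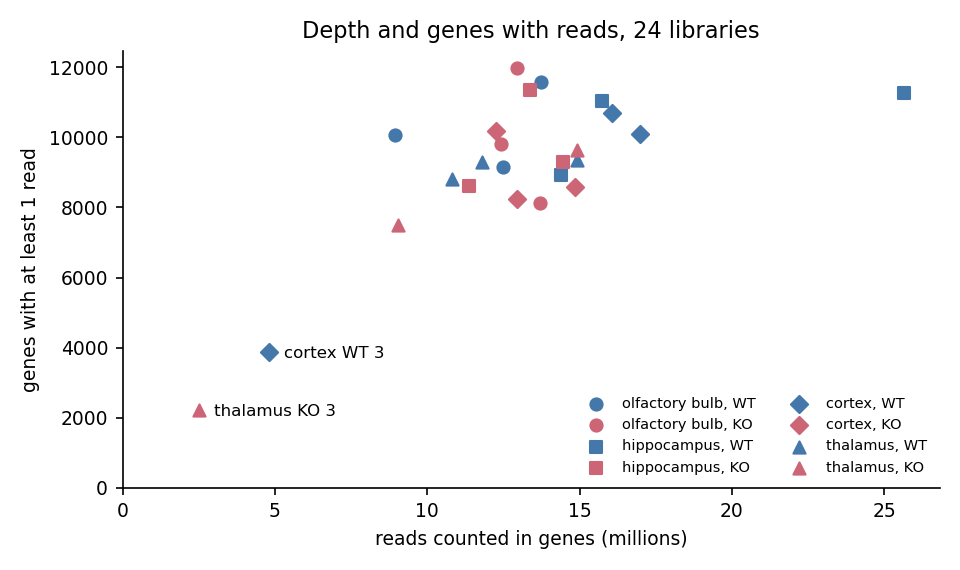
Genes with at least 1 read (vertical axis) against reads counted in genes (horizontal axis), with a point per library, shapes for regions and colours for genotype labels. Cortex WT replicate 3 (3871 genes) and thalamus KO replicate 3 (2220 genes) lie below the range of 7509 to 11984 genes of the other libraries.

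Hippocampus WT replicates 2 and 3 held the same genes to a degree that no other pair of libraries did. Not 1 of the 8364 genes at 50 or more normalized reads in either was at 0 in the other, whereas 1536 of 8854 were for replicates 1 and 2, and at least 850 were for each of the other 275 pairs. Over 7838 genes with a mean of at least 50, the log2 ratio of replicate 2 to replicate 3 (pseudocount 10) stayed between -3.92 and 2.11. The other pairs reached at least 7.46 upwards and -7.36 or lower downwards. The correlation of log2 values across genes was 0.885 for this pair and at most 0.716 for the others. Their reads still differed by more than sampling noise (median chi-square 88.6 per gene), so they were kept as separate libraries, and values with the pair averaged as 1 library stand beside the hippocampus calls.

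**Figure D3:**
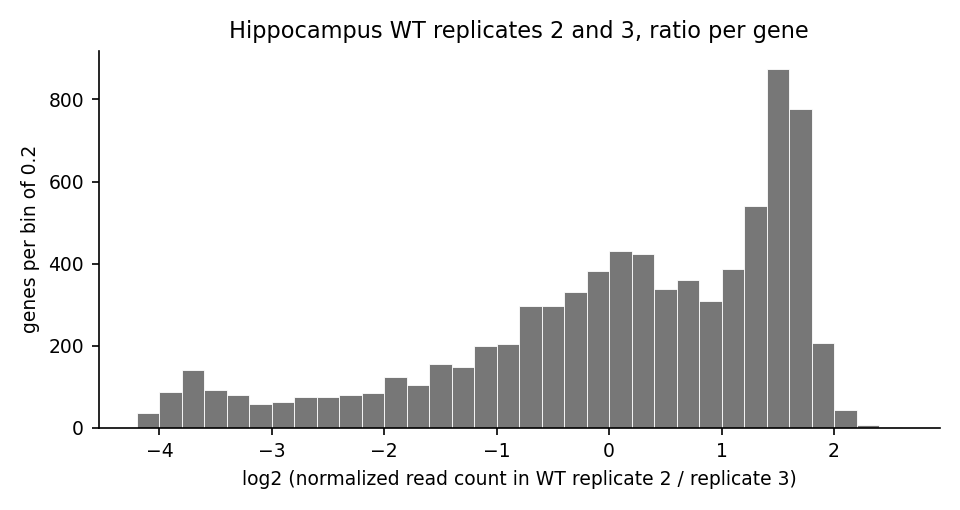
Histogram of the log2 ratio of hippocampus WT replicate 2 to replicate 3 (horizontal axis, without a pseudocount) against the number of genes (vertical axis), for genes with a mean of at least 50 normalized reads. The ratios end at both sides in a peak, with 875 genes from 1.4 to 1.6 and 142 from -3.8 to -3.6.

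In the olfactory bulb the genes with the smallest p-values included Ncan, which encodes the matrix proteoglycan neurocan, and Smo, the signal transducer of the Hedgehog pathway. Ncan stood at 64220 ± 1261 normalized reads in WT and 100848 ± 34349 in KO (SD, n = 3), a log2 difference of 0.59 (SE 0.18), and was the 1 of 27 tested synapse-regulating factors to pass adjusted over the list alone (limma, adjusted p = 0.0316). It did not pass over all genes (limma, adjusted p = 1.00). Smo stood at 4435 ± 4924 in WT and 504 ± 460 in KO (log2 difference -3.82, SE 0.95). The others, with log2 differences in parentheses, were Rassf2 (-2.34), Acsf2 (-2.97), Parva (2.39), Tubgcp3 (-3.81), Arhgef10 (-2.73), Lix1 (-3.96), Ptbp1 (-3.06) and Ric3 (1.92). Among astrocyte identity genes 12 of 26 lay above 0 and 14 below (median -0.10), with the glutamate transporter Slc1a2 at 302199 ± 41691 in WT and 267532 ± 47670 in KO. Of 20 tested GABA genes 7 lay above and 13 below (median -0.18), led by the GABA-B receptor subunit Gabbr2 (-2.30, SE 1.15), Gabarap (-1.26), Gabrg3 (-1.29) and Maob (-1.16). Of 11 tested purinergic genes 4 lay above and 7 below (median -0.21), led by the nucleoside transporter Slc29a2 (3.55, SE 1.87), the ATP-gated channel P2rx7 (-2.09, SE 1.16), Calhm2 (1.41) and the adenosine receptor Adora2b (-1.52). No GABA, purinergic or astrocyte identity gene passed adjusted over the list alone. Limma called 0 genes higher and 0 lower of 9385, and 376 had an unadjusted p under 0.05 where chance gives 469. Run on the recovered reads, limma-voom and edgeR called 0, and DESeq2 called 79 higher and 81 lower. Camera in limma placed no list apart from the other genes (smallest adjusted p = 0.569), and 9.06% of genes had groups that did not overlap, where chance gives 10%. Without KO replicate 2, limma called Ncan higher and Smo lower (adjusted p = 0.00110 and 0.0254).

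In the hippocampus Tubb4a, a beta-tubulin gene abundant in myelinating oligodendrocytes and neurons, fell in KO. It stood at 4887 ± 1315 normalized reads in WT and 544 ± 363 in KO (SD, n = 3), a log2 difference of -3.30 (SE 0.66, limma, adjusted p = 0.0307), with all 3 KO libraries below all 3 WT libraries. With WT replicates 2 and 3 averaged its log2 difference was -3.19 and the call was lost (limma, adjusted p = 0.484). It was lost as well without WT replicate 2 (adjusted p = 0.640), without WT replicate 3 (adjusted p = 0.478) and without KO replicate 3 (adjusted p = 0.0611), and in 11 of 23 alternatives in all (adjusted p from 0.0001 to 1 in limma and the other tools). Nnat, which encodes the membrane protein neuronatin, was named after its values were seen. Nnat stood at 10750 ± 4001 in WT and 1887 ± 1414 in KO and missed the threshold with all 6 libraries (-2.98, SE 0.61, limma, adjusted p = 0.123). With the pair averaged it was the 1 gene called (-3.13, limma, adjusted p = 0.00168), and it was called with each of the 6 libraries left out in turn (log2 difference -3.59 to -1.95, adjusted p from 0.00125 to 0.0254). Tubb4a lies on chromosome 17 at 57080066 to 57087782 (minus strand, GRCm38), where no other annotated gene overlaps it. Nnat lies on chromosome 2 at 157560078 to 157562522 (plus strand) and its exons overlap the span of the antisense gene Blcap. Overlap with the exons of Blcap was not examined, so a mixing of their reads was not settled.

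Oligodendrocyte markers had lower mean log2 values in hippocampus KO than in WT, though not in every library. All 13 tested lay below 0 (median -1.59), whereas Mbp took 940, 5825 and 966 CPM in the KO libraries and 1635, 2513 and 1849 in the WT libraries. Of these markers the myelin gene Mal (-2.34, SE 0.72) passed adjusted over the list alone (limma, adjusted p = 0.0107, and 0.0495 with WT replicates 2 and 3 averaged), and camera in limma gave adjusted p = 0.00391 for the list. The camera call was lost with an estimated correlation (adjusted p = 0.920 with an estimated correlation), and with WT replicates 2 and 3 averaged the preset test gave adjusted p = 0.00360 and the other adjusted p = 0.915 with an estimated correlation. Of 16 tested GABA genes 7 lay above and 9 below (median -0.13). Gabbr2 stood at 1845 ± 671 in WT and 420 ± 650 in KO. Adjusted over the list alone, limma gave it an adjusted p of 0.0151, which was lost with the pair averaged (adjusted p = 0.0669). The aldehyde dehydrogenases Aldh1a1 (0.94, SE 0.45) and Aldh5a1 (-1.24, SE 0.62) did not pass. Of 9 tested purinergic genes 5 lay above and 4 below (median 0.39), with adenosine kinase, Adk, at 1.54 (SE 0.86), P2ry12 at -1.32, Adora2b at 1.94 and the ectonucleotidase Entpd1 at -1.07, and 0 passed adjusted over the list alone. The calcium channel subunit Cacna1d (-5.66, SE 1.33, limma, adjusted p = 0.00103 over the list alone, and 0.0220 with the pair averaged) was the 1 of 18 calcium genes to pass over its list. Astrocyte identity genes had 7 of 26 above and 19 below (median -0.18, camera in limma, adjusted p = 0.366). Limma called 0 genes higher and 1 lower of 9213, with 578 at an unadjusted p under 0.05 where chance gives 461. With the pair averaged, 283 of 8298 genes had an unadjusted p under 0.05 in limma, and the excess over chance was gone. On the recovered reads limma-voom and edgeR called 0 and DESeq2 248 higher and 270 lower, or 456 higher and 182 lower with the reads of WT replicates 2 and 3 summed. Groups did not overlap for 12.1% of genes, where chance gives 10%. Leaving out 1 library gave 1 to 7 lower calls, with 5 without WT replicate 1, 2 without KO replicate 1 or KO replicate 3, and 7 without KO replicate 2.

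In the cortex astrocyte genes stood higher and neuronal genes lower in KO than in WT, and cortex WT replicate 3 held few of the former and many of the latter. Of 26 astrocyte identity genes 24 lay above 0 (median 0.81), among them the lipid enzyme Acsbg1 (3.32, SE 1.08), the gap junction gene Gjb6 (2.64), Aldh1l1 (3.61) and the glutamate transporter Slc1a3 (0.65). Camera in limma gave adjusted p = 7.7e-07, and adjusted p = 0.819 with an estimated correlation. Of 17 tested GABA genes 16 lay above 0 (median 1.37, camera in limma, adjusted p = 0.00690, or adjusted p = 0.819 with an estimated correlation), led by Gabrg1 (2.72), Aldh5a1 (2.86), Aldh1a1 (2.76) and Gabra2 (2.89). Of 14 potassium, water and ion genes 13 lay above 0 (median 0.72, camera in limma, adjusted p = 0.000437, or adjusted p = 0.819 with an estimated correlation). Of 9 astrocyte markers 8 lay above 0 (median 1.21, camera in limma, adjusted p = 2.6e-06, or adjusted p = 0.819 with an estimated correlation). Of 7 neuronal markers 6 lay below 0 (median -2.25, camera in limma, adjusted p = 0.000293, or adjusted p = 0.336 with an estimated correlation), and the synaptic vesicle gene Syp passed adjusted over the list alone (0.00986, limma), at 24682 normalized reads in WT replicate 3 and 194 to 605 in the other WT libraries. Oligodendrocyte markers had 3 of 12 above 0 and 9 below (median -0.61, camera in limma, adjusted p = 0.0354, or adjusted p = 0.819 with an estimated correlation). Without WT replicate 3 no list in this comparison passed. Astrocyte identity then had a median of -0.03 (camera in limma, adjusted p = 0.629), astrocyte markers -0.02 (0.451), GABA genes -0.17 (0.896), potassium, water and ion genes -0.16 (0.896), neuronal markers -1.60 (0.451) and oligodendrocyte markers -0.43 (0.896). The median of all genes was 0.49 with deposited factors, 0.60 with TMM factors, -0.11 with upper-quartile factors and -0.29 without WT replicate 3.

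Purinergic genes in the cortex had 5 of 11 above 0 and 6 below (median -0.02), led by P2rx4 (3.27, SE 1.85), the adenosine receptor Adora1 (-2.67), Enpp2 (-1.61) and Entpd1 (2.56), and 0 passed adjusted over the list alone. Glycogen synthase, Gys1, was the 1 of 16 metabolic coupling genes to pass over its list (limma, adjusted p = 0.0497), at 1743 ± 1610 in WT and 3.89 ± 6.07 in KO, and the collagen gene Col1a1, at 1284 ± 2037 in WT and 0 in all 3 KO libraries, and Lum, at 0 in all 3 WT libraries and 312 ± 178 in KO, did so among 3 fibroblast markers (limma, adjusted p = 0.0306). Without WT replicate 3, Syp and Col1a1 were too low to be tested, Gys1 no longer passed over its list (limma, adjusted p = 0.0903), and Lum (0.0232), Clu (0.0149) and Igf2 (0.0175) did. The 10 genes with the smallest p-values, none of which passed, were Syp, Gys1 and Acsbg1, named already, the transcriptional repressor Zbtb20 (3.84), Cep170 (-3.54), Nucb1 (-6.35), the amyloid precursor gene App (-3.32), Cfl1 (2.20), Dpysl2 (3.45) and the serine synthesis enzyme Psat1 (3.46). Limma called 0 genes higher and 0 lower of 8376, with 204 at an unadjusted p under 0.05 where chance gives 419, and 0 without WT replicate 3. On the recovered reads limma-voom called 0 higher and 2 lower, edgeR 1 higher and 8 lower, and DESeq2 30 higher and 69 lower. Groups did not overlap for 7.61% of genes, where chance gives 10%.

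In the thalamus the genes with the smallest p-values and higher KO means were Ly6a, a surface antigen gene of endothelial and immune cells, the calpain subunit gene Capns1 (3.47) and Mobp, a myelin gene, and their KO means rested on KO replicate 3. Ly6a stood at 237134 normalized reads in KO replicate 3 and at 11.6 ± 14.0 in WT (n = 3), Capns1 at 131296 ± 221147 in KO and 1525 ± 418 in WT, and Mobp at 56471 ± 83059 in KO and 2800 ± 2994 in WT. The median log2 difference of all 7675 tested genes was -1.31, so most members of a list below 0 do not by themselves set it apart. Of 26 astrocyte identity genes 23 lay below 0 (median -1.17, camera in limma, adjusted p = 0.0351, or adjusted p = 0.874 with an estimated correlation), led by Gpr37l1 (-3.48), the bicarbonate transporter Slc4a4 (-2.34), the connexin gene Gja1 (-1.77) and Mlc1 (-3.37). Of 14 potassium, water and ion genes 13 lay below 0 (median -1.48, camera in limma, adjusted p = 0.000985, or adjusted p = 0.748 with an estimated correlation). GABA genes had 15 of 19 below 0 (median -1.90, camera in limma, adjusted p = 0.134), led by Aldh1a1 (-3.72), the GABA transporter Slc6a13, at 1053 ± 1201 in WT and 0 in all 3 KO libraries, and Gabrg1 (-3.37). Purinergic genes had 8 of 11 below 0 (median -1.75), led by P2rx7, at 297 ± 352 in WT and 0 in all 3 KO libraries, Entpd1 (2.39), Adora2b (-2.55) and P2ry13 (-2.43). Immediate early and dissociation genes had 14 of 22 above 0 (median 1.68, camera in limma, adjusted p = 0.000282, or adjusted p = 0.541 with an estimated correlation), and endothelial markers 8 of 8 (median 2.00, adjusted p = 0.000721, or adjusted p = 0.541 with an estimated correlation). Neuronal markers had 6 of 7 above 0 (median 1.04) and oligodendrocyte markers 5 of 12 (median -0.18), and both had camera adjusted p = 0.0302 upwards in limma, or adjusted p = 0.541 with an estimated correlation. For oligodendrocyte markers the median and the test thus differ in sign. No member of these lists passed adjusted over the list alone.

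Without thalamus KO replicate 3, the library with 2220 genes, none of these thalamus lists passed. Astrocyte identity had a median of -0.19 (camera in limma, adjusted p = 0.859), potassium, water and ion genes -0.38 (0.626), GABA genes 0.06 (0.928), purinergic genes 0.41 (0.324), immediate early genes 0.25 (0.626), endothelial markers 1.69 (0.0898), neuronal markers 0.34 (0.644) and oligodendrocyte markers 0.21 (0.928). The lists that passed without it were the NFI family (median 1.17, camera in limma, adjusted p = 0.00729), fibroblast markers (-1.42, 0.0253) and choroid plexus markers (1.39, 0.0187), each with adjusted p = 0.752 with an estimated correlation. With all 6 libraries these had 2 of 4, 1 of 8 and 2 of 7 members above 0. Adjusted over the list alone without KO replicate 3, the fibroblast markers Igf2 (limma, adjusted p = 0.00455), Dcn (0.0316) and Slc6a13 (0.0316) passed. So did the microglia marker Csf1r (0.00919) and the calcium gene Atp2a2 (0.0377). Slc6a13 passed among the fibroblast markers and not among the GABA genes. The other genes with the smallest p-values in the 6 libraries were Thumpd1, at 1760 ± 1239 in WT and 0 in KO, Tro, at 1208 ± 903 in WT and 0 in KO, Lrrc58 (-2.99), Arhgap5 (-2.84), the ankyrin gene Ank2 (-3.97), Aldh1a1 and Spop (-6.26). Limma called 0 genes higher and 0 lower of 7675, with 293 at an unadjusted p under 0.05, 27 of them higher and 266 lower, where chance gives 384. It called 0 without KO replicate 3. On the recovered reads of 4 libraries limma-voom and edgeR called 1 higher and 0 lower, and DESeq2 336 higher and 487 lower. The median of all genes was -1.31 with 6 libraries and -0.18 without KO replicate 3, and 11.2% of genes had groups that did not overlap, where chance gives 10%.

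The genotype difference averaged over the 4 regions, a comparison chosen after the data were seen, called no gene. The 10 genes with the smallest p-values were Rpe65, a retinoid isomerase gene, at 169 ± 448 in WT and 797 ± 787 in KO (n = 12, log2 difference 3.47, SE 0.89), Pitpnm2 (-3.35), Zfp953 (-3.03), Arfip2 (-3.21), Ccndbp1 (3.17), Tspan6 (-2.85), Zak (-2.97), the paranodal adhesion gene Cntnap1 (-2.56), Dock5 (-3.05) and Tubb4a (-2.42, SE 0.74). All had an adjusted p of 0.983 in limma. Limma called 0 genes higher and 0 lower of 12477, with 604 at an unadjusted p under 0.05 where chance gives 624. On the recovered reads of 22 libraries limma-voom called 0 higher and 1 lower, Slc1a2 (-0.36), edgeR called 0, and DESeq2 called 215 higher and 303 lower. For Nfix limma gave 0.70 (SE 0.56, adjusted p = 0.997).

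No list stood apart in the average over regions (camera in limma, smallest adjusted p = 0.3596), and no member of any list passed adjusted over the list alone. Members above and below 0 numbered 2 and 2 for the NFI family, 9 and 17 for astrocyte identity, 8 and 17 for GABA signalling, 6 and 8 for purinergic signalling, 7 and 9 for glutamate uptake and receptors, and 6 and 11 for potassium, water and ion homeostasis. They numbered 6 and 20 for calcium signalling, 8 and 22 for synapse-regulating factors, 6 and 12 for gap junctions and metabolic coupling, 13 and 14 for cholesterol and lipid synthesis, 16 and 11 for reactive astrocyte genes, and 17 and 9 for interferon response and antigen presentation. The remaining pathway lists had 8 and 16 for neural stem cell and radial glia genes, 8 and 8 for the cell cycle, 17 and 13 for immediate early and dissociation genes, 9 and 25 for extracellular matrix and adhesion, 11 and 15 for cell shape and cytoskeleton, and 8 and 17 for regional patterning factors. Among cell type markers, astrocytes had 4 and 5, neurons 1 and 11 (median -0.68), neuroblasts and interneurons 4 and 7, oligodendrocyte precursors 5 and 3, oligodendrocytes 2 and 11 (median -0.76), microglia 7 and 7, and macrophages and other leukocytes 4 and 3. Endothelial cells had 5 and 7, mural cells 5 and 4, fibroblasts 3 and 5, ependymal cells 2 and 3, choroid plexus epithelium 5 and 2, and olfactory ensheathing cells 3 and 4. None of the 5 erythrocyte markers was detected well enough to be tested. The members with the smallest p-values were Gabbr2 (-2.05, SE 0.87) among GABA genes and P2rx7 (-1.86, SE 0.90) among purinergic genes.

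In the 21 libraries left without cortex WT replicate 3 and thalamus KO replicate 3 and with the hippocampus pair averaged, the average over regions again called 0 of 12347 genes in limma (633 at an unadjusted p under 0.05, smallest adjusted p = 0.479). All 4 NFI genes lay above 0 (median 0.47, camera in limma, adjusted p = 0.00791, or adjusted p = 0.358 with an estimated correlation). Adjusted over the list alone, Nfix (0.85, SE 0.26, limma, adjusted p = 0.00577), Gabbr2 (-1.94, SE 0.57, adjusted p = 0.0234) and the lipoprotein gene Clu (-0.54, SE 0.15, adjusted p = 0.0192) passed. GABA genes had 8 of 24 above 0 and 16 below (median -0.18), and purinergic genes 7 and 7 (median 0.11). Tubb4a stood at -1.57 (SE 0.40) and Rpe65 at 3.56 (SE 0.86).

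No gene had a KO against WT difference that differed between the regions when all 24 libraries entered (limma, 0 of 12477, 572 at an unadjusted p under 0.05 where chance gives 624). DESeq2 called 15 genes, limma-voom 19 and edgeR 1, Lhx2, on the recovered reads of 22 libraries. Without a filter on low values limma called 9. The genes with the smallest p-values were Slc6a13, Nr2c2, Napg, Slc25a42, Lrrtm4, Entpd4, Zdhhc1, Thumpd1, Kbtbd11 and Smg9 (limma, adjusted p = 0.939 for each). For the GABA transporter Slc6a13 the log2 differences were 1.24 in the olfactory bulb, 0.33 in the hippocampus and 0.33 in the cortex, and in the thalamus its KO libraries were all at 0. Without cortex WT replicate 3 and thalamus KO replicate 3, limma called 1 of 12424, Hapln1 (adjusted p = 0.00679), which encodes a link protein of the hyaluronan matrix. Its log2 differences were then -0.34, 0.23, -0.18 and 6.06 in the same order, and with the hippocampus pair also averaged Hapln1 was again the 1 gene called (of 12347, limma, adjusted p = 0.0196). The next genes were Cyth2, Nr2c2, Lhx2, Gemin8, Adam23, Ubn1, Ttc30a1, Zdhhc1 and Ece1, none of which passed.

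Among the 12 WT libraries, 28 genes differed between the regions, 20 of them highest in the olfactory bulb, 5 in the thalamus, 2 in the cortex and 1 in the hippocampus (limma F test, 28 of 11105, smallest adjusted p = 5.37e-06). Slc6a11, which encodes the GABA transporter GAT-3, stood at 52745 ± 15157 normalized reads in the olfactory bulb and 38541 ± 10047 in the thalamus, against 9019 ± 2370 in the hippocampus and 8496 ± 5045 in the cortex (SD, n = 3). Fabp7, a fatty acid binding protein of radial glia and olfactory ensheathing cells, stood at 35298 ± 4151 in the olfactory bulb and between 1404 ± 466 and 2875 ± 805 elsewhere. Kctd12, an auxiliary subunit of GABA-B receptors, stood at 29417 ± 2272 in the olfactory bulb and 389 ± 115 in the thalamus, and the apolipoprotein gene Apod at 22806 ± 2590 and 8097 ± 2458. Prrg3 stood at 3063 ± 611 in the olfactory bulb and was at 0 in the 9 libraries of the other regions. The thalamus was low in Chrdl1, a secreted regulator of synapse maturation (33.8 ± 36.6, against 8365 ± 1911 in the olfactory bulb), in Adam23 (73.2 ± 127), in the forebrain patterning factor Lhx2 (8.22 ± 13.5, against 7667 ± 7905 in the cortex, or 3135 there without WT replicate 3) and in Hapln1 (4.59 ± 7.10). It was high in the matrix glycoprotein gene Sparc, at 47603 ± 9800 against 6752 ± 3575 in the cortex. The other called genes were Gria1, Clca3a1, Frzb, Ptn, Clu, Fam171b, Igf2, Slc35f1, Fndc1, Sema5a, Sdk2, Slc6a13, Sgcd, Gdpd4, Dcn, Lrrtm4, Clca3a2 and Zic1. Clca3a1 and Clca3a2 are near-identical copies whose reads the counting could have split.

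**Figure D4:**
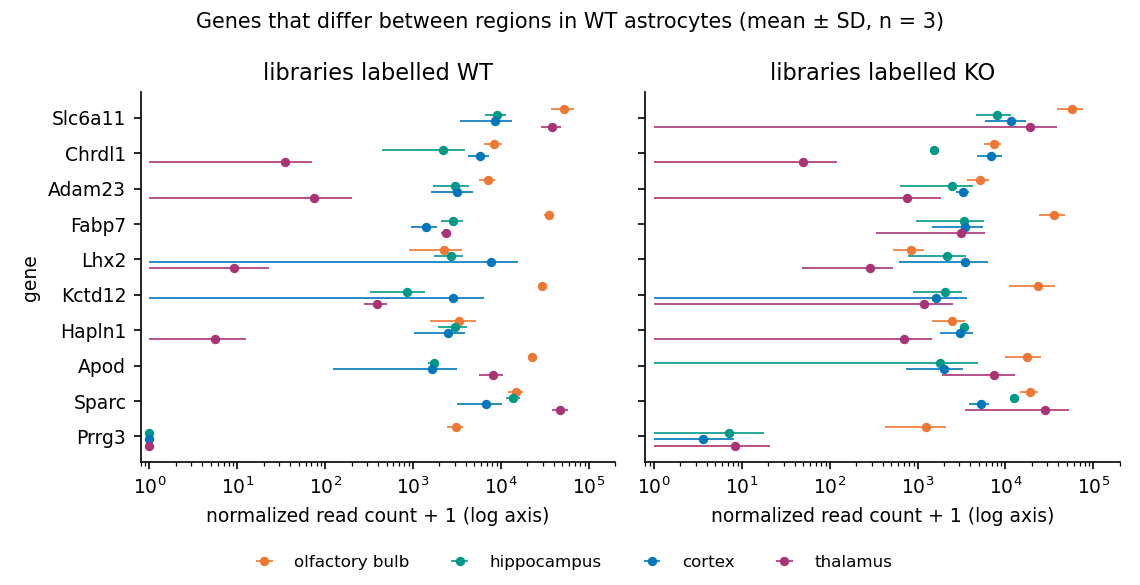
Mean normalized read count + 1 (log axis) in the 4 regions of the 10 named genes that differ between regions in the WT libraries, in libraries labelled WT (left) and KO (right), with the SD as whiskers (n = 3) that end at 1 where the SD exceeds the mean. In WT, Slc6a11 is high in olfactory bulb (52745) and thalamus (38541), and Chrdl1, Adam23, Lhx2 and Hapln1 are low in thalamus.

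By list, the regional genes included 2 of 22 tested GABA genes (Slc6a11 and Slc6a13), 3 of 29 synapse-regulating factors (Chrdl1, Hapln1 and Sparc), 2 of 24 patterning factors (Lhx2 and Zic1), 3 of 6 fibroblast markers (Igf2, Slc6a13 and Dcn), 2 of 5 ensheathing cell markers (Fabp7 and Frzb) and 0 of 13 purinergic genes. Adjusted over the list alone these counts were 2, 6, 6, 4, 4 and 2, the last being P2ry1 and Entpd1, and 6 of 6 choroid plexus markers passed. Ensheathing cell markers were higher in the olfactory bulb than in the hippocampus (median log2 difference 4.87, camera in limma, adjusted p = 0.0270 with an estimated correlation), the cortex (4.72, adjusted p = 0.0347 with an estimated correlation) and the thalamus (6.70, adjusted p = 0.0133 with an estimated correlation). Fibroblast markers were higher in the thalamus than in the cortex (median -5.39 for cortex minus thalamus, camera in limma, adjusted p = 0.0226 with an estimated correlation). Pairs of regions differed by 11 genes higher and 1 lower for olfactory bulb against hippocampus, 8 and 1 against cortex, and 14 and 0 against thalamus. Hippocampus against cortex gave 0 calls in limma, hippocampus against thalamus 4 and 1, and cortex against thalamus 7 and 6. Without cortex WT replicate 3 the pairs gave, in this order, 33 and 14, 19 and 10, 76 and 27, 3 and 0, 37 and 19, and 28 and 20. At an unadjusted p under 0.05 the F test had 754 genes. Without cortex WT replicate 3 it called 140 of 11047 genes, which included all 28, with 67 highest in the olfactory bulb, 29 in the thalamus, 27 in the cortex and 17 in the hippocampus. Among them were 7 of 26 astrocyte identity genes, such as Slc1a2 (302199 ± 41691 in the olfactory bulb, 647660 ± 40481 in the hippocampus, 688508 ± 26579 in the other 2 cortex libraries and 266123 ± 25295 in the thalamus). With the hippocampus pair averaged it called 18. DESeq2 called 215 genes, limma-voom 383 and edgeR 237 on the recovered reads of 11 libraries.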

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

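The tests of Hapln1 between regions, of the hippocampus pair, of Nfix, of the share of other tissue in the thalamus and of the splits in DESeq2 were chosen after the results were seen. Hapln1 stands out for a difference between groups: without the libraries with few detected genes its KO against WT difference differed between regions (limma F test, adjusted p = 0.00679, and 0.0196 with the hippocampus pair also averaged).

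Thalamus KO replicates 1 and 2 held genes that were low in thalamus WT and present in the other regions. Hapln1 stood at 0.993, 0 and 12.8 normalized reads in the WT libraries and 1549 and 518 in these KO libraries, and Lhx2 at 23.8, 0.823 and 0 against 417 and 431. One explanation is that the genes were picked for low values in WT, and each WT library was held out of the choice in turn. The score was the median share of the way from thalamus to hippocampus and cortex WT levels. Over genes lower or higher in the thalamus, both KO libraries lay above the held-out library in 1 of 3 rounds. Over the lower genes alone, held-out libraries had 0.345, 0.248 and 0.339. KO replicate 1 had 0.344, 0.377 and 0.348, and KO replicate 2 had 0.149, 0.124 and 0.149. Such picking fits the pattern of the set. Hapln1 and Lhx2 were low in every WT library, but low WT values were how such genes were picked. The rounds therefore do not decide for Hapln1 and Lhx2. In thalamus KO replicate 3 each stood at 9.90 normalized reads, the value of 1 read there. Tissue of cortex or hippocampus in the KO samples may also contribute, and its share could not be bounded closely (upper 95% bound 0.742 from 8 abundant genes), so it cannot be told apart. A change with genotype in the thalamus remains possible and was not separated from these.

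Hippocampus WT replicates 2 and 3 shared their detected genes. The same library deposited under 2 names is excluded, since the reads differed by more than sampling (median chi-square 88.6 with 1 degree of freedom). Reads of each library also being counted in the other would bound the ratio of values, and the highest log2 ratio was 2.11, so such mixing fits, before or after sequencing. No biological explanation was tested.

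Nfix was higher in the libraries labelled KO as deposited, and turned in the cortex under upper-quartile scaling (-1.53). That scaling gave no value for the thalamus. Scaling does not account for the average, since the lowest of 4 scalings over 22 libraries was 0.84. The exact permutation (p = 0.000138) excludes chance assignment only if all libraries are independent, which the labels do not show. It counted the hippocampus WT pair as separate libraries and was not run with the pair averaged. In limma the average was 0.70 (SE 0.56, unadjusted p = 0.215). Without the libraries with few detected genes and with the pair averaged, limma gave 0.85 (SE 0.26, unadjusted p = 0.00144). Exchanged genotype labels would place KO libraries above the WT libraries of their region, as 10 of 12 were, but an allele that leaves a transcript without the deleted exons at a raised level would do so too. The values per gene cannot tell these apart. All directions given for KO therefore rest on the labels.

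Other splits of the 6 libraries of a region are too few to exclude chance. In limma 10 of 10 splits called as many genes as the real one in the olfactory bulb (real 0, highest other 0), 3 in the hippocampus (real 1, highest other 4), 10 in the cortex (real 0, highest other 1) and 10 in the thalamus (real 0, highest other 0). In DESeq2 7 of 10 did so in the olfactory bulb (real 160, highest other 499), 3 in the hippocampus (real 518, highest other 1022) and 8 in the cortex (real 99, highest other 492). In the olfactory bulb and cortex the highest other split called several times the real count, and whether this reflects a structure of the samples or unstable calls at 3 libraries a side was not tested. In the hippocampus, splits with WT replicates 2 and 3 on one side called 513 to 1022 genes in DESeq2 and splits that parted them 7 to 36. For the average over regions and for the interaction 100 of 100 drawn splits called as many genes as the real one (real 0, highest other 1 in both). Where the real count is 0 every split calls as many, so these splits, like those of limma in the olfactory bulb, cortex and thalamus, carry no information on chance. For the WT regions 1 of 100 splits, the real one, called as many (real 28, highest other 10). The real grouping keeps hippocampus WT replicates 2 and 3 together, whereas drawn splits could part them. With this pair averaged 18 genes were called, and no splits were drawn in that setting. The splits therefore exclude chance only if the 2 libraries are independent.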

How the results depend on the processing

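Of the main results, 380 values kept their direction and side of the threshold, 59 moved, 1 turned and 1 became stronger. Of the others, 14838 stayed, 1275 moved, 94 became stronger, 68 weaker and 2 turned. The losses of the hippocampus Tubb4a call count among these weaker values and not among the main results. Where values moved or turned, the cause was not tested unless the setting itself shows it. Counts are higher and lower in KO.

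In the olfactory bulb (0 and 0) DESeq2 called 79 and 81, and all libraries in one model 0 and 2 (Lrrc18 and Lrrtm4 lower). Leaving out 1 library gave 0 to 1 higher and 0 to 1 lower. In the hippocampus (0 and 1) DESeq2 called 248 and 270, DESeq2 with the reads of WT replicates 2 and 3 summed 456 and 182, and array weights 5 and 18. Lower calls were 0 with upper-quartile factors, limma-voom, no filter, all libraries in one model, pseudocount 1 or edgeR. They were 6 with the strict filter, 2 without robust estimation and 3 with pseudocount 100, and 1 to 7 with 1 library left out. Tubb4a ranged from -3.80 to -2.96 over 23 alternatives (limma and other tools, adjusted p from 0.0001 to 1), keeping its call in 12. In the cortex (0 and 0) Nfix turned to -1.53 with upper-quartile factors, DESeq2 called 30 and 69, limma-voom 0 and 2 (Clu and Cpe), and edgeR 1 and 8. Leaving out 1 cortex library gave 0 and 0.

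In the thalamus (0 and 0) DESeq2 called 336 and 487 on 4 libraries, limma-voom 1 and 0 (Slc1a2, which turned to 0.20), edgeR 1 and 0 (Ttc30a1), limma without robust estimation 2 and 0 (Mbp and Rn45s), and all libraries in one model 0 and 1 (Slc6a13). Leaving out 1 library gave 0 to 1 higher and 0 lower. The median of choroid plexus markers in the thalamus went from -3.54 without WT replicate 1, where camera turned downwards, to 1.62 without WT replicate 2. For the average over regions (0 and 0) DESeq2 called 215 and 303, with Nfix at 0.80 and past the threshold, and limma-voom 0 and 1. For the interaction (0) DESeq2 called 15, limma-voom 19, no filter 9, edgeR 1, and limma without the libraries with few detected genes 1, with the hippocampus pair averaged as well 1 (Hapln1 in both). For the WT regions (28) upper-quartile factors gave 4, DESeq2 215, limma-voom 383, edgeR 237, the averaged hippocampus pair 18, and leaving out the cortex library with few genes 140. Leaving out 1 library gave 14 to 140.

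With the replicate number as a block the hippocampus had 3 lower calls (Tubb4a, Nnat and Cnot4), the WT regions had 26 calls, 25 of them among the 28, and the other counts stayed at 0. Within regions, same-numbered WT and KO libraries correlated at -0.0693 to 0.0731, and 6 of 12 WT libraries correlated best with their own number. Between regions, same-numbered KO libraries correlated at -0.0521 to 0.107 (mean 0.0225, against -0.0113 for other numbers). For WT libraries the means were 0.00286 and -0.00146. The numbers were thus not shown to pair the libraries, and whether 1 animal gave several regions was not settled. Upper-quartile factors could give no value for the thalamus and for all 24 libraries, where a library's quartile was 0, and in the cortex the quartile of WT replicate 3 was close to 0. Count tests left out 2 thalamus libraries, WT replicate 1 and KO replicate 3, where 1 read was worth close to 1 and to 10. Pseudocounts 1 and 100, TMM, edgeR, array weights, the pair settings and the settings without few-gene libraries were added after seeing the data. Depth limits low genes most in thalamus KO replicate 3 (3 reads at 1.19 CPM).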

Other observations

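The genes that differed between regions in the WT libraries mostly kept their regions in the libraries labelled KO, in a test chosen after the WT result was seen. They include markers of ensheathing cells (Fabp7 and Frzb) and of fibroblasts (Igf2, Slc6a13 and Dcn). Differences between astrocytes were not separated from differences in such other cells. Of these 28 regional genes, 25 were highest in the same region in KO, where chance gives 7, and 26 differed in the same direction. Their mean log2 difference was 4.28 in KO and 6.17 in WT. Genes and regions were chosen in WT, which raises the WT value, so these means do not show weaker differences in KO. An exact one-sided permutation of the region labels of the 12 KO libraries gave p = 0.000108 (40 of 369600 assignments). Regional differences shared by both genotypes would give such a result. The exceptions in direction were Sparc (-0.96, but 3.05 without thalamus KO replicate 3, where it was at 0) and Slc6a13 (-1.24 in both), and 25 genes kept their region without thalamus KO replicate 3, with a mean of 3.78.

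Summed choroid plexus markers ranged from 0.625 to 95809 CPM between libraries. Ttr, which encodes transthyretin, made by choroid plexus epithelium, took 92162 CPM in thalamus WT replicate 2, 54663 in hippocampus KO replicate 2 and 34442 in thalamus KO replicate 1, and at most 55.0 in the olfactory bulb. The summed choroid plexus markers averaged 6972 ± 5632 CPM in hippocampus WT and 21675 ± 30245 in hippocampus KO, and 34496 ± 53220 and 15706 ± 18063 in the thalamus. Ensheathing cell markers summed to 4107 ± 258 CPM in olfactory bulb WT and 4055 ± 1613 in KO, and to at most 522 in any library of the other regions. Erythrocyte markers stayed at or below 0.438 CPM.

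The KO against WT differences of the 4 regions were nearly unrelated across genes, with a mean correlation of 0.0191 in the 22 libraries other than cortex WT replicate 3 and thalamus KO replicate 3 (pairs from -0.00140 to 0.0299 over 12424 genes). In 4 of 100 splits, the real one included, the mean was as large (highest other 0.0259). All assignments of genotype within regions, counted after this result was seen, gave an exact one-sided permutation p of 0.0488 (1951 of 40000 as large), and 0.04865 with the hippocampus pair averaged. With all 24 libraries the mean was 0.00124 (exact p = 0.431), so chance is not excluded.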
